A study of Mus musculus with 2 samples.

How the data were processed

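DNase-seq was performed on adrenal gland tissue of 2 male B6CASTF1/J mice aged 25 days, with 1 library per animal, and both libraries were sequenced on the same pair of Illumina instrument models per the labels. The labels number the animals separately and call them biological replicates, while giving both the same donor code. Nuclei were isolated by a protocol that the labels link to. For each library, 2 deposited peak lists, a list of false discovery rates along the genome and a list of footprints were analysed, all in mm10 and made from that library's own filtered alignments. The aligner, the peak and footprint callers, their versions and the filters are not given in the sources used here. Alignments and signal tracks named in the file descriptions were not analysed here.

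Peak height is a deposited signal value, and per the file headers and the values it was scaled by the authors to a library total, since all heights were whole multiples of 1 step per library within a tolerance of 0.01 of a step. The step was 0.00833 in replicate 1 and 0.00888 in replicate 2, which, read as CPM values, gives totals of 120 and 112.6 M counts, an inference from the values. The median height corresponded to 121 and 81 steps. The deposited FDR (q-value) list gives stretches with an FDR of at most 0.05, and every deposited footprint carries the same FDR threshold of 0.01, so footprints have no score of their own. Each peak of the longer list held a position at an FDR of 0.05 or less, and each of the shorter list 1 at 0.001 or less. The stretches at 0.05 covered 37.1 and 35.8 Mb, and 64.5% and 47.8% of those bases were at 0.001.

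Gene lists, consensus sequences, comparisons, the rule for naming genes and most alternative settings were fixed before the data were examined. The plan named the file of narrower peaks as the main one, and the longer list, with mean widths of 172.8 and 149.3 bp against 178.5 and 166.6 bp, was taken on that ground once the widths were known. Genes came from GENCODE release M21 on GRCm38.p6, and 21829 protein-coding genes with 54321 starts were used, with repeated symbols dropped. Bmal1 was looked up under its older symbol Arntl. A promoter was open when a peak touched the 1 kb on either side of any protein-coding start of the gene, and its height was that of the strongest such peak. Such a peak can lie at an alternative start, or nearer to a neighbour's start. Other DHSs were assigned to the nearest protein-coding start within 100 kb of their centre, and the number assigned is the DHS load.

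The 24 lists covered steroid hormone synthesis, adrenocortical regulators, zona glomerulosa, zona fasciculata, X-zone, chromaffin cells, adrenal capsule and fibroblasts, Schwann and sustentacular cells, endothelium, macrophages, lymphocytes, erythroid cells, adipocytes, gonadal steroidogenic and Sertoli cells, kidney, liver, brain neurons, skeletal muscle, keratinocytes, housekeeping, circadian clock, immediate early response, cholesterol synthesis and uptake, and imprinted genes. Per library, a list's count of open promoters, its median load (random genes matched on decile of territory length) and the median log2 ratio of summed height, replicate 2 over replicate 1, each scaled to its library's total (matched on decile of mean signal), were set against 10000 random lists of the same size. A list stood apart at a percentile of at least 97.5 or at most 2.5, in both libraries where each had its own. Percentiles describe these libraries and are not p-values across animals. Named genes were the first 4 of the 6 cortical and chromaffin lists, the first 2 of each other list, the 10 genes with the highest load, the genes at the 5 strongest shared DHSs and the 5 with the largest ratio each way among genes of above-median signal. Other list members were named only as exceptions, and some genes that this rule takes are left out of the text.

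Overlap between libraries needed 1 bp, beside the mean of 20 random placements outside assembly gaps. Each of 25 consensus sequences was searched on both strands in DHSs and in windows of equal length 2 kb away on each side that touched no DHS. Footprints with 5 bp added on each side were compared with random windows in the same DHS that touched no footprint, and log2 ratios used a pseudocount of 0.5. Shares carry 95% Wilson intervals, which cover counting error only, since neither sites nor sequencing reads are independent animals. Alternatives were other promoter windows and distance limits, the 50000 strongest DHSs, stricter overlap, CpG-matched, GC-matched or unmatched backgrounds, other scalings and each library alone. The shorter peak list for all results but the overlap, DHSs nearest to the gene's own start and merged sites were added after seeing the data.

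The procedures were tested on simulated data. Of the promoter lists, 2 of 2 made to differ were called and 0 of 22 others, and for DHS load 1 of 1 and 0 of 23. In these promoter and load simulations the 2 libraries were drawn independently. The real libraries agreed closely, with 65.8% of genes open in both against 69.4% and 69.2% in each. The absence of other calls therefore does not give the rate of false calls in the data. A change of 1 list by a log2 of 1 in signal was recovered as 1.05, and 3.12% of lists were called where nothing had been changed. An overlap set at 60% was recovered as 60.6% and a motif log2 ratio of 2.01 as 1.99. The parents' alleles were not separated. Near-identical gene copies and repeats make single heights uncertain. Software was bedtools 2.31.1, samtools 1.23.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.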

Results

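Chromatin accessibility was measured by DNase-seq in adrenal glands of 2 male mice aged 25 days. DNase-seq cuts DNA in nuclei with the enzyme DNase I, so that stretches cut often, called DNase I hypersensitive sites (DHSs), mark open chromatin such as active promoters and enhancers. The mice were B6CASTF1/J hybrids, that is, F1 offspring of the strains named B6 and CAST. The adrenal gland has a cortex that makes steroid hormones and a medulla of chromaffin cells that makes catecholamines. Both libraries belong to a single group, replicate 1 and replicate 2, so the data describe the open sites of this tissue and how far the 2 animals differed. No second tissue or treatment was compared, no p-value could be given, and values are reported for each library in turn. Positions are in mm10, and a height is the deposited peak signal, which was a whole multiple of 1 step in each library. Read as CPM values, these steps correspond to totals of 120 M counts in replicate 1 and 112.6 M counts in replicate 2. The longer deposited lists held 130945 DHSs covering 22.6 Mb in replicate 1 and 157786 DHSs covering 23.6 Mb in replicate 2, with median heights of 1.01 and 0.720.

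Genes of steroid hormone synthesis were open in both animals. Star, which carries cholesterol into mitochondria, had a promoter DHS of height 7.55 in replicate 1 (chromosome 8, 25806381 to 25806560) and 4.02 in replicate 2. Cyp21a1, the 21-hydroxylase gene, had promoter heights of 1.67 and 1.53, although its near-identical pseudogene makes these values uncertain. Cyp11a1, which cleaves the cholesterol side chain, had its strongest promoter DHS at an alternative start 8589 bp inside the gene (chromosome 9, 58014901 to 58015100), with heights of 6.23 and 1.80. No DHS touched the 1 kb on either side of its 5′ end in either library. The nearest DHS centres lay 2445 bp (replicate 1) and 1499 bp (replicate 2) downstream, so the gene counted as open only away from its 5′ end. Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase gene with close copies in the genome, had no promoter DHS in either library. Of the 15 genes of this list, 13 had a promoter DHS in both libraries, all but Hsd3b1 and Cyp11b2. That count lay at percentiles 92.4 and 92.8 of 10000 random lists, within their range, and at 99.9 and 99.7 when the random genes were matched on the CpG content of their promoters. Matching mattered because CpG-rich promoters are open in most tissues.

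**Figure D1:**
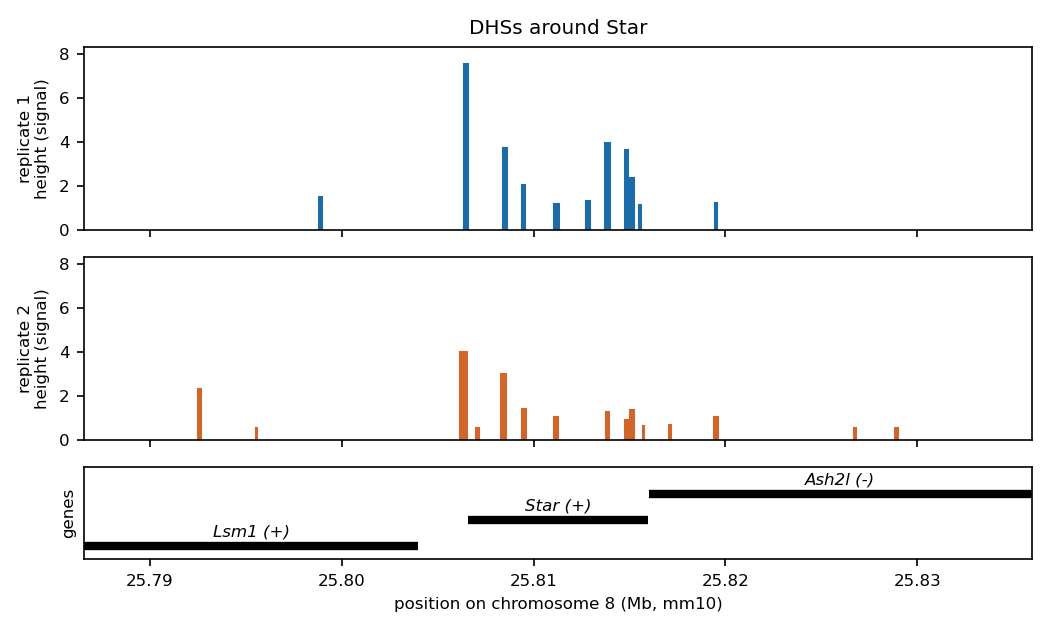
DHSs around Star on chromosome 8 (x axis, Mb in mm10) in replicate 1 (top) and replicate 2 (middle), drawn as bars at their true width with the deposited height on the y axis, above the protein-coding genes (bottom). Replicate 1 had 11 DHSs in the window of 20 kb on either side of the gene and replicate 2 had 15, and 8 in each overlapped one of the other library.

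Regulators of the adrenal cortex were open throughout. All 11 genes of the list had a promoter DHS in both libraries, at percentiles 99.2 and 99.2 of random lists. Nr5a1, which encodes the steroidogenic factor SF-1, had promoter heights of 9.01 and 4.09 (chromosome 2, 38714441 to 38714600 in replicate 1). Within the gene, an intronic DHS 7702 bp downstream of the 5′ end (38706741 to 38706940) had heights of 3.85 and 3.13. Mrap, an accessory protein of the corticotropin receptor, had heights of 8.38 and 5.26. The receptor gene Mc2r itself had only weak promoter DHSs, at 0.458 and 0.666, which lay at different positions in the 2 libraries. Nr0b1, the DAX-1 gene on chromosome X, had heights of 0.867 and 0.675. This list no longer stood apart with the shorter peak list (mean percentile 97.3) or among the 50000 strongest DHSs (92.9).

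Most markers of the cortical zones had a promoter DHS. All 10 genes of the zona fasciculata list, the layer that makes glucocorticoids, had a promoter DHS in both libraries (percentiles 98.7 and 98.8, but 94.8 and 96.6 with the shorter peak list). Cyp11b1, the 11-beta-hydroxylase gene, had heights of 2.18 and 1.57, Akr1b7 had 3.71 and 2.48, and Abcb1b had 5.46 and 3.94. In the zona glomerulosa list, the aldosterone-producing outer layer, 12 of 15 genes were open in both libraries, at percentiles 98.1 and 80.7, so this list did not stand apart. Wnt4, a signal of the outer cortex, had heights of 9.60 and 4.44, Agtr1b had 1.23 and 0.835, and Dab2 had 4.78 and 3.77 at a start 86922 bp from its 5′ end. Cyp11b2, the aldosterone synthase gene, had no promoter DHS in either library, with the caveat that it is a close copy of Cyp11b1. The 4 genes of the X-zone, a transient inner layer of the mouse cortex, were all open (percentiles 88.1 and 88.6), and 3 and 2 of them with the shorter peak list (62.0 and 32.0). With all 4 open, 88.1 and 88.6 were the highest percentiles attainable, so this list could not stand apart on the high side. Thrb, a thyroid hormone receptor, had heights of 9.72 and 5.51 and Cyp2f2 had 1.36 and 1.82. Akr1c18, the 20-alpha-hydroxysteroid dehydrogenase gene, was weak at 0.60 and 0.711. Pik3c2g was weaker still, at 0.317 and 0.489, over different alternative starts in the 2 libraries. The zone, steroid and cholesterol lists share genes (8 of 10 fasciculata genes are in another of them), so their counts are not independent.

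Most chromaffin cell genes had a promoter DHS in both libraries. Th and Dbh, enzymes of catecholamine synthesis, had promoter DHS heights of 1.37 and 1.13 for Th (at an alternative start) and 1.05 and 0.80 for Dbh. Chga, the chromogranin A gene, had 5.67 in replicate 1 and 2.48 in replicate 2. In all, 19 of 23 genes of the list were open in both, and Pnmt, Ddc and Hand1 were among those without a promoter DHS in either. These counts lay within the range of random lists (percentiles 91.4 and 91.9, and 46.3 and 55.8 with random genes matched on CpG content). With the shorter peak list, 19 genes were open in replicate 1 and 13 in replicate 2.

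**Figure D2:**
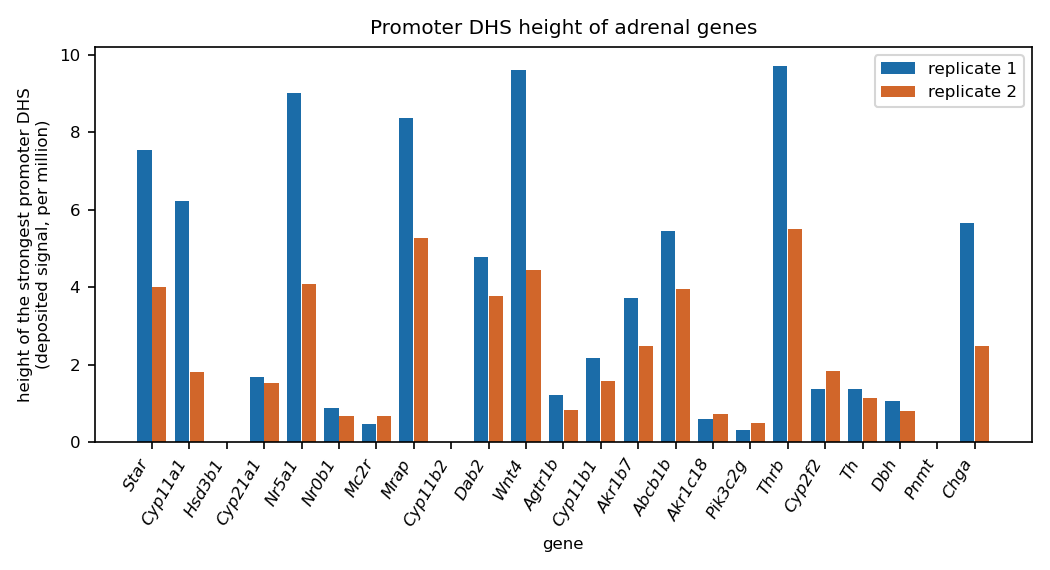
Height of the strongest promoter DHS (y axis, deposited signal) of the genes named from the steroid, regulator, zone and chromaffin lists (x axis), with 1 bar for each replicate. Wnt4, Thrb and Nr5a1 were the tallest in replicate 1, and Hsd3b1, Cyp11b2 and Pnmt had none.

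Most endothelial promoters were open, and among organ lists kidney and liver stood apart on the low side. Endothelial genes were open at 12 of 13 promoters in each library, including Pecam1 (0.575 and 0.995, at an alternative start 35405 bp from its 5′ end) and Cdh5 (1.23 and 1.12). The list lay at percentiles 96.6 and 96.9, and at 98.3 and 98.4 with random genes matched on CpG content. With the shorter peak list 8 and 7 of 13 were open (percentiles 38.1 and 27.6), Pecam1 and Cdh5 not among them. The capsule and fibroblast list was open at 9 of 12 promoters in both, with Gli1, a marker of capsular cells, at 6.04 and 3.12 and Tcf21 at 0.433 in replicate 1 alone. Of 8 Schwann and sustentacular genes, 4 were open in both, and Sox10 had no promoter DHS in either. The adipocyte list was open at 7 of 9 promoters in both, at percentiles 89.4 and 89.7, and 99.0 and 98.8 with CpG matching, where it stood apart as the steroid list did. With the shorter list 7 and 4 were open (percentiles 76.9 and 15.7). Among its genes, Plin1, a lipid droplet protein, had 5.53 and 1.48 at an alternative start and Adipoq 0.720 in replicate 2 alone. Liver genes were open at 3 of 12 promoters in both and kidney genes at 2 of 10. The liver genes Alb and Apoa1 and the kidney genes Umod and Slc12a1 had no promoter DHS. The erythroid list was open at 2 of 8 promoters in both, where Klf1 had a DHS of 0.817 in replicate 2 alone. Among gonadal genes, 6 of 11 were open in both, with Cyp17a1, absent from the steroid pathway of the adult mouse adrenal, at 0.792 in replicate 1 alone and Hsd17b3 in neither. For the neuronal list the count was 6 of 10 (Slc17a7 1.46 and 1.09, Neurod6 0.453 in replicate 2 alone). Skeletal muscle genes were open at 3 of 9 promoters in both. Ckm had 5.97 and 4.56 at an alternative start 6184 bp inside the gene, Myod1 had 0.717 in replicate 1 alone, and the DHS in the Actn3 window lay nearer to the start of Zdhhc24. Keratinocyte genes were open at 1 of 8 in both, and Krt5 (0.675) and Trp63 (0.426) in replicate 2 alone. With random genes matched on CpG content no list stood apart on the low side, since many tissue markers have CpG-poor promoters.

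More lymphocyte promoters were open in replicate 2 than in replicate 1. Of 8 lymphocyte genes, 1 promoter was open in replicate 1 and 6 were open in replicate 2, at percentiles 0.0900 and 62.0. With the shorter peak list 0 and 2 were open, and the list stood apart on the low side in both libraries (percentiles 0.0200 and 2.33). Cd3e, of the T-cell receptor complex, had no promoter DHS in replicate 1 and a height of 0.577 in replicate 2. Of 11 macrophage genes, 1 was open in replicate 1 and 4 in replicate 2, and this list stood apart on the low side in both. Csf1r and Ptprc had no promoter DHS in either library, but Ptprc, the CD45 gene, had 3 DHSs assigned to it in replicate 1 and 9 in replicate 2 (3 and 4 with the shorter list).

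Broadly active gene sets were open in full. All 16 housekeeping genes, all 16 circadian clock genes, all 12 immediate early genes, all 18 genes of cholesterol synthesis and uptake and all 12 protein-coding imprinted genes had a promoter DHS in both libraries, each list at percentile 99.3 or above. Heights were high for Actb (22.6 and 17.0), Gapdh (12.9 and 12.8), the clock genes Per1 (19.5 and 15.6, at different starts) and Nr1d1 (24.0 and 14.1), and Egr1 (24.2 and 13.4). Fos had 6.93 and 5.65, Sqle 16.2 and 11 and the imprinted gene Peg3 13.1 and 6.5. H19, Kcnq1ot1 and Meg3, imprinted RNAs without protein product, were left out of that count and had promoter heights of 0.750 and 0.737, 5.63 and 4.81, and 4.70 and 2.92. With random genes matched on CpG content, the housekeeping, clock, immediate early and cholesterol lists no longer stood apart, whereas the regulators, fasciculata and imprinted lists did. Over all 21829 protein-coding genes, 69.4% and 69.2% were open at a promoter.

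**Figure D3:**
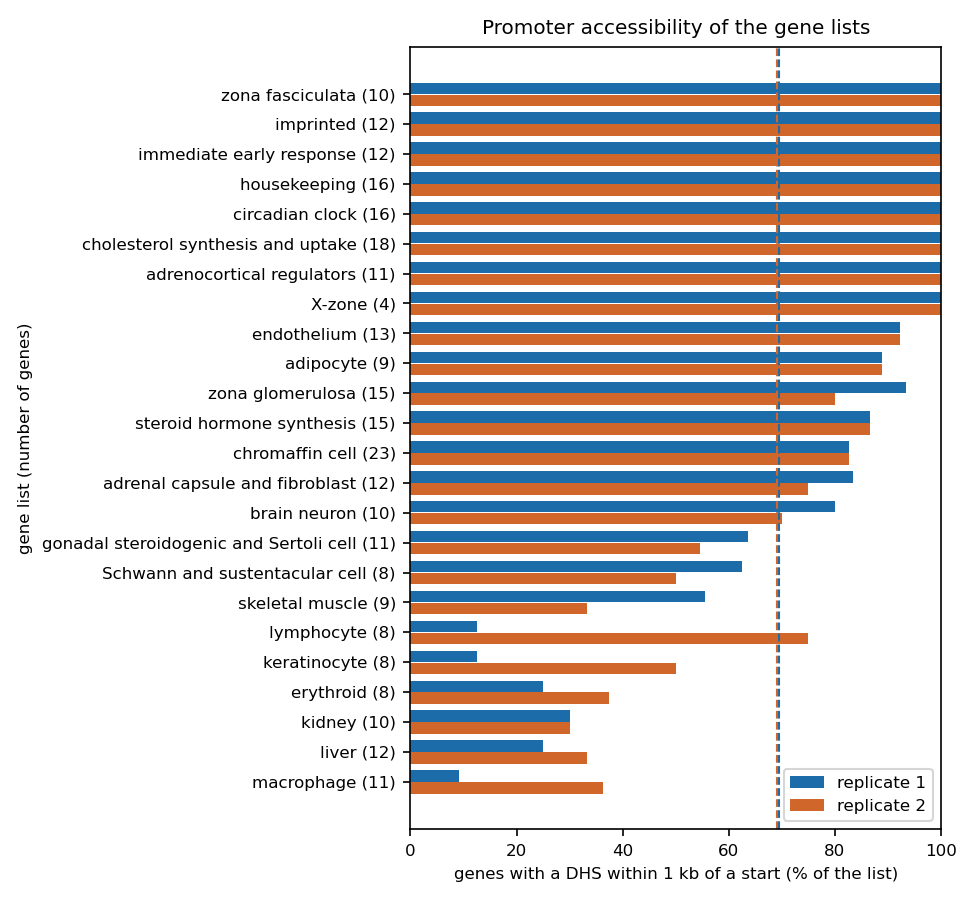
Share of each gene list with a DHS within 1 kb of a protein-coding start (x axis, percent of the list), for replicate 1 and replicate 2, with the number of genes in brackets. Dashed lines mark all protein-coding genes (69.4% and 69.2%), and the lymphocyte list has the widest gap between the replicates, with 1 and 6 of 8 genes open.

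Steroidogenic genes were also surrounded by many DHSs. The median number of DHSs assigned to a gene of steroid hormone synthesis was 9 in replicate 1 and 11 in replicate 2, against medians of 3 and 4 in random lists matched on the size of the gene's territory (percentiles 99.98 and 100). Star had 11 and 11 and Cyp11a1 had 12 and 22. Immediate early genes had medians of 16 and 15 against 4.5 and 5, with Fos at 23 and 15. Clock, housekeeping and imprinted lists also stood apart on the high side, and kidney on the low side (1 and 0.5 against 3 and 3.5). The fasciculata, regulator, glomerulosa and endothelium lists passed in 1 library each. With the shorter peak list 3 lists stood apart (clock, immediate early and imprinted), and steroid synthesis, at percentiles 95.2 and 99.3, did not, nor did it among the 50000 strongest DHSs (mean percentile 98.5). Among the genes with the highest mean number were Pde4d (77 and 84), Gse1 (77 and 64), Tns1 (70 and 55), Sept9 (62 and 54), Foxp1 (54 and 58), Frmd4a (53 and 57), Ank3 (50 and 56), Kcnma1 (55 and 50) and Auts2 (59 and 45). This ranking was not adjusted for gene length or number of starts, and several of these genes are long. Pde4d, for example, runs from 108449948 to 109953461 on chromosome 13.

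Promoters held a minority of sites but most of the signal. Of DHSs in replicate 1, 23.4% (95% Wilson interval 23.2 to 23.6) lay within 1 kb of a protein-coding start, 5.86% in exons, 33.3% in introns and 37.5% between genes. In replicate 2 the shares were 19.5% (19.3 to 19.7), 5.23%, 31.3% and 43.9%. Promoter DHSs carried 52.5% and 51.7% of the summed height, with median heights of 2.68 and 2.00 against 0.783 and 0.524 between genes. These intervals cover counting error only, and the promoter share was 41.3% on average among the 50000 strongest DHSs. The 5 strongest shared DHSs were near Gm21887 on chromosome X (169998241 to 169998400, heights 83.2 and 89.1), at the promoter of Hjurp on chromosome 1 (58.1 and 42.9), near Gm11168 on chromosome 9 (48.0 and 71.4), and at the promoters of Nup107 on chromosome 10 (52.9 and 39.8) and Dynlt1b on chromosome 17 (53.4 and 33.0). The middle 36 bases of the Gm11168 site occurred 25 times in the reference and those of the Gm21887 site 2 times, so these heights can include signal from other copies.

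The strongest sites were shared by both animals and the weakest were not. In replicate 1, 62.2% of DHSs overlapped a DHS of replicate 2 by at least 1 bp, and in replicate 2, 51.8% overlapped one of replicate 1, against 2.02% and 1.69% after random placement. Among the strongest 10% of sites, 99.6% and 98.8% were shared, and among the weakest 10%, 16.0% and 4.65%. Across 82852 overlapping pairs, log2 heights correlated with Pearson's r of 0.892 and Spearman's rho of 0.857. This correlation is across sites, which are not independent replicates. Heights in replicate 2 were lower, with a median log2 ratio of replicate 2 over replicate 1 of -0.34 and an SD over sites of 0.69. Replicate 2 had more DHSs than replicate 1 in the longer list but fewer in the shorter list (65480 against 81558).

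Sensory receptor families, which most tissues keep silent, had more open promoters in replicate 2. Promoters of 1133 olfactory receptor genes held a DHS in 3.71% of genes in replicate 1 and 13.5% in replicate 2. Vomeronasal receptor genes were open at 0.606% and 2.73% of 330. With the shorter list the olfactory shares were 1.41% and 2.12% and the vomeronasal shares 0.606% and 0.303%. These families hold many near-identical genes, so single promoters are uncertain.

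When the signal around each gene was compared between the animals, most gene lists did not differ beyond random lists. The Schwann and sustentacular list was lower in replicate 2, with a median log2 ratio of -0.70 over 8 genes (percentile 0.290 of random lists matched on signal), and 2 of its 8 genes were higher. Sox10 had -0.92. With 24 lists, 1.2 are passed by chance. This call was not made when DHSs were counted, when shared DHSs alone were used or with promoter DHSs alone, so it rests on the setting. Those settings called other lists, namely liver and skeletal muscle lower in replicate 2 by counts, zona glomerulosa and macrophage lower and housekeeping higher with shared DHSs, and X-zone higher with promoter DHSs (0.79, percentile 99.1, 3 of 4 genes higher). With the median ratio as scale, the Schwann list was called and kidney was higher (percentile 97.9). With the shorter peak list, 5 lists were lower in replicate 2, namely zona glomerulosa (-0.38), zona fasciculata (-0.34), chromaffin (-0.58, with 4 of 20 genes higher), capsule and fibroblast (-0.56) and adipocyte (-0.57). In the same animals the lymphocyte list had 1 and 6 of 8 promoters open. Steroid synthesis had -0.15, the regulators -0.05, cholesterol 0.18, housekeeping 0.14 and all genes 0.03, within the range of random lists. The covered length was 22.6 and 23.6 Mb and the mean height 2.55 and 1.61 in the compared lists.

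The largest ratios of single genes fell at starts that lie close together. Lower in replicate 2 were Gpatch11 (log2 -5.46), Sugct (-3.63), Pip4p1 (-3.45), Swi5 (-2.93) and Mgat2 (-2.68), and higher were Gm9903 (4.02), Heatr5b (3.89), Zfp277 (3.73), Tada2b (3.51) and Golga2 (3.46). Their promoter DHSs nevertheless had similar heights in both libraries, for example 28.7 and 23.6 at the DHS shared by Gpatch11 and Heatr5b, and 22.2 and 16.6 at the DHS shared by Swi5 and Golga2. With the DHSs of both libraries merged into common sites, so that each site went to 1 gene, Sugct turned from -3.63 to 3.30 and the others ranged from -0.08 (Mgat2) to 1.5 (Zfp277).

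DHSs held more CTCF sites and sites of promoter-binding factors than flanking windows. The CTCF consensus was found in 4.14% of DHSs in replicate 1 (4.03 to 4.25) and 2.79% in replicate 2 (2.71 to 2.88), against 0.0349% and 0.0341% of flanking windows, log2 ratios of 6.88 and 6.35. Ratios were also high for EGR (4.85 and 4.93), NRF1 (4.26 and 4.0), NFI (4.17 and 3.60), SP/KLF (3.39 and 3.37), ETS (3.01 and 3.24), CRE (2.75 and 2.77) and AP-1 (1.73 and 1.63). With windows matched on GC content, EGR had 1.1 and 1.11 and SP/KLF 1.18 and 1.26. The SF-1 consensus YCAAGGYCA occurred in 4.42% and 3.43% of DHSs against 2.23% and 1.75% (0.99 and 0.97), under the log2 threshold of 1. Its mean log2 ratio was 1.43 over 1 kb from a start, 1.25 with GC matching, 0.76 with the shorter list and 0.48 among the 50000 strongest DHSs. The PHOX2 paired site of sympathetic neurons was scarcer in DHSs than in flanks (-2.43 and -2.66), as was GATA (-0.51 and -0.40). With GC matching this scarcity was not seen, with 1.24 and -0.07 for PHOX2 and a mean of 0.37 for GATA. The HNF1 consensus of liver and kidney had 0 matches in DHSs of either library, with upper limits of 0.00293% and 0.00243%. Flanking windows held it in only 0.000401% and 0.00132%, below those limits. The consensus was thus too rare to tell DHSs from flanks. DHSs had a mean GC content of 56.4% and 54.2% against 44.8% and 43.5% in flanks, and consensus matches are not evidence of binding.

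**Figure D4:**
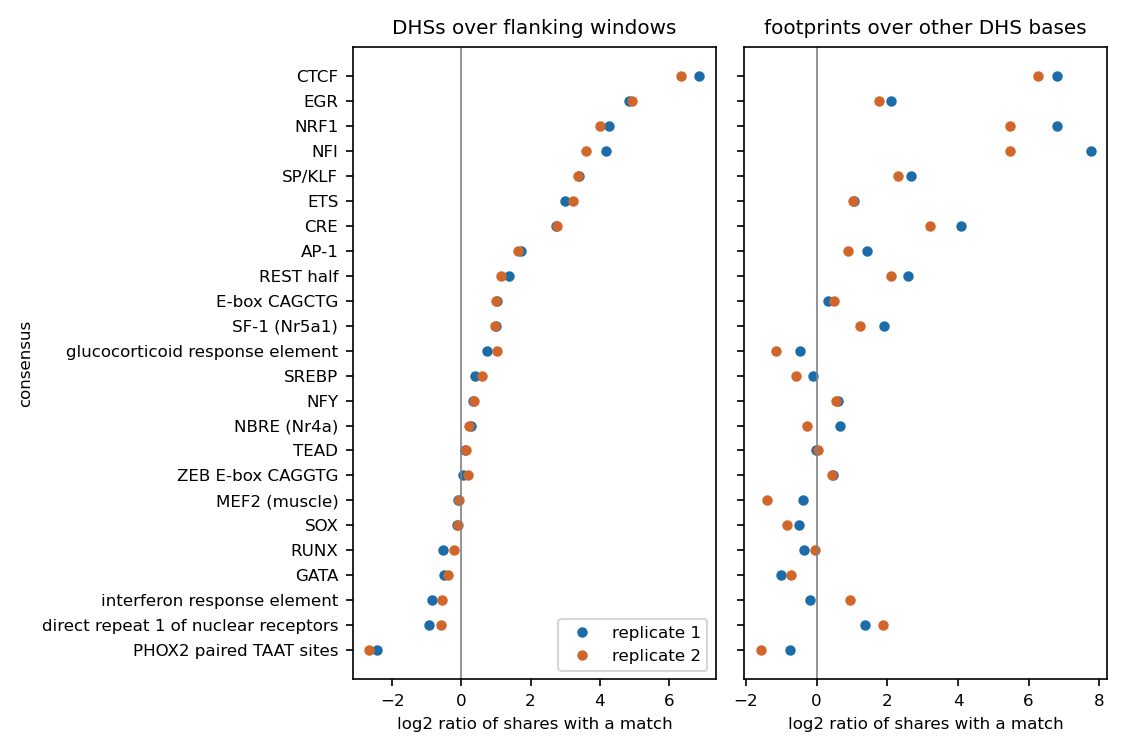
Log2 ratio of the share with a consensus match (x axes) in DHSs over flanking windows (left) and in footprints over other bases of the same DHSs (right), for each consensus (y axis) and each replicate. CTCF leads the left panel at 6.88 and 6.35, and SF-1 is at 1.91 and 1.23 in the right panel.

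Footprints, short stretches protected from cutting inside DHSs, pointed to a similar set of factors. Replicate 1 had 272597 footprints and replicate 2 had 184847, of which 90.1% and 95.1% lay in DHSs. Of the footprints, 28.6% and 45.3% overlapped one of the other library. Within DHSs the shares were 30.2% and 45.4%, against 11.9% and 17.3% after random placement among the DHSs of the same library. Footprints were not kept in the DHS they came from, so part of this gap can reflect which DHSs are shared. The SF-1 consensus was found in 0.878% and 0.564% of footprints in DHSs against 0.234% and 0.240% of other windows there, log2 ratios of 1.91 and 1.23. CTCF had 6.79 and 6.27, NRF1 6.80 and 5.47, CRE 4.08 and 3.21 and SP/KLF 2.67 and 2.30. NFI had 7.75 and 5.47, where the background held 0 matches in replicate 1, so that ratio depends on the pseudocount of 0.5. At Cyp11a1, 2 SF-1 matches overlapped footprints of both libraries by at least 1 bp. One was TGACCTTGA in an intergenic DHS at -2907 bp from the 5′ end (chromosome 9, 58003500 to 58003508), and the other TCAAGGCCA in an intronic DHS at 2738 bp (58009145 to 58009153). A further match at Cyp11a1, CCAAGGTCA (58011780 to 58011788), lay in a DHS of replicate 2 alone and under no footprint. At the chromaffin gene Dbh, the match TGGCCTTGG (chromosome 2, 27161693 to 27161701) lay in a DHS of replicate 1 alone, with a height of 0.833, and under no footprint. DHSs within 20 kb of Star, Mrap and Th held no match. The match CCAAGGCCA in an intron of Nr5a1 (chromosome 2, 38705210 to 38705218) lay in a DHS in both libraries, with heights of 1.62 and 2.06, and under no footprint.

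Chromosome X had fewer DHSs per Mb than the autosomes in both males. The density was 22.0 DHSs per Mb in replicate 1 and 39.5 in replicate 2, 0.413 and 0.627 times that of the autosomes. Among the autosomes of replicate 1 the lowest density was 41.2 on chromosome 3 and the highest 79.6 on chromosome 11. Counted as DHSs within 1 kb of a protein-coding start, for each such start, the ratio was 0.914 and 0.907. Among the 50000 strongest DHSs it was 0.256 and 0.233, and males carry 1 copy of chromosome X.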

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

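The shorter peak list (except for the DHS overlap), DHSs nearest to the gene's own start and merged sites were chosen as alternatives only after the data were seen. Mean overlap of DHSs, 57.0%, was 49.5% with 50% of each peak required, 79.7% among the 50000 strongest and 69.4% with the shorter list. Pearson's r of 0.892 was 0.844 in the stronger part of the pairs (a narrower range of heights) and 0.889 with the shorter list. The promoter share of 21.5% was 16.7% with 500 bp, 27.0% with 2.5 kb, 41.3% among the 50000 strongest, 34.0% with the shorter list and 19.5 to 23.4% in single libraries. Of 24 lists, 10 stood apart by open promoters, 6 with CpG-matched random lists (3 of them among the 10), 11 to 14 in single libraries and 9 to 12 otherwise. With CpG matching, the housekeeping, clock, immediate early and cholesterol lists, open in full, could not reach the threshold. By DHS load 6 stood apart, 3 with the shorter list, 8 in each single library and 5 to 9 otherwise. By difference between replicates 1 stood apart, 2 with counts, 3 with shared DHSs, 2 with the median ratio as scale and 5 with the shorter list. Footprint overlap of 36.9% was 21.5% with 50% of each required. Motifs past a log2 of 1 numbered 10 in DHSs (8 to 11 under the alternatives, 10 to 11 in single libraries) and 10 in footprints (9 to 11, and 10 to 11). The chromosome X ratio of 0.520 was 0.910 per start, 0.244 among the 50000 strongest and 0.413 to 0.627 in single libraries. Where no ground is given, the cause was not tested. Single lists kept their call in 162 cases for promoters (17 gained, 13 lost), 121 for load (13 and 10) and 121 for difference (12 and 4). Single motifs moved by more than the spread in 80 of the DHS cases and 32 of the footprint cases. No called list reversed, while GATA and PHOX2 sites in DHSs turned from means of -0.46 and -2.55 to 0.37 and 0.59 with GC-matched windows. Whether other consensus sequences changed sign under that setting is not listed here. A stricter set of footprints could not be run, since each carries the same FDR threshold of 0.01. With 1 group of 2 animals, no paired analysis was possible because there was no second condition.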

Other observations

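Of the tests here, those on depth, on receptor promoters, on the height of leukocyte promoters and on the largest ratios were chosen only after the result was seen, and those on CTCF and AP-1 and on a second leukocyte list were set before their result was seen. Leukocyte genes outside the fixed lists were open more often in replicate 2. Of 37 further genes, 15 promoters were open in replicate 1 and 33 in replicate 2, 18 of them in replicate 2 alone and 0 in replicate 1 alone. With the shorter peak list 8 and 25 were open. Rac2 and Cd79b, of leukocyte and B-cell signalling, had no promoter DHS in replicate 1 and heights of 2.97 and 2.28 in replicate 2. Cd74, of antigen presentation, had none and 2.02, Vav1 0.925 and 3.81, Ptpn6 0.983 and 3.42, and Ikzf1 2.21 and 3.43. Relative to shared DHSs, 29 were higher in replicate 2 and 4 lower (among them Pax5, Gmfg and Fcgr3), while Btk, Lcp2, Fcer1g and Csf2rb were closed in both.

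Chromaffin genes differed between the replicates with the shorter peak list and not with the longer. Relative to shared DHSs, 14 promoters of the longer list were lower and 5 higher in replicate 2 (percentile 21.7). With the shorter list 19 promoters were open in replicate 1 and 13 in replicate 2, and the signal around the genes had a median log2 ratio of -0.58 (percentile 0.160).

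Replicate 2 had more DHSs than replicate 1 in the longer list but fewer in the shorter list. The ratio of their numbers was 1.21 in the longer list and 0.803 in the shorter, which restates the pattern. A lower sequencing depth alone was predicted to shorten both lists. The totals read from the heights were close, at 120 M counts in replicate 1 and 112.6 M in replicate 2. These values argue against lower depth as the only source, although the totals are an inference and a part played by depth stays open. Library-specific distal DHSs held a CTCF or AP-1 match in 9.98% of replicate 1 and 4.30% of replicate 2, a ratio of 0.431. The prediction for regulatory sites of animal 2 alone, a share at least as high in replicate 2, was not met. Such sites stay open all the same, since width and GC content also differed and sites of other factors are not counted by this share. SF-1 (3.71% and 2.07%) and NFI (0.197% and 0.0384%) sites were scarcer too, ETS (0.224% and 0.229%), RUNX (1.29% and 1.47%) and interferon response (0.0549% and 0.110%) sites were not, and GC content (53.74% and 49.96%) and median width (140 and 120 bp) differed. Receptor promoters were open 3.68 times as often in replicate 2 (162 against 44, and 25 against 18 with the shorter list), so lower enrichment with more diffuse weak peaks may account for additional weak sites.

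More lymphocyte promoters (6 against 1 of 8) and macrophage promoters (4 against 1 of 11) were open in replicate 2 than in replicate 1. The 8 promoters open in replicate 2 alone had a median of 1.17 against 0.378 for 140 receptor promoters open there alone, percentile 100 of random sets. Diffuse weak peaks like those at receptor promoters thus do not account for the median height. Single heights ran from 0.497 (Ms4a1) to 3.07 (Laptm5), so such peaks stay open for the lower ones. Other promoters open in replicate 2 alone were not compared. The second leukocyte list had a median log2 ratio of 2.55 (random lists -0.33 to 0.08, percentile 100), with closed promoters set at the library's lowest height, so more blood or lymphoid cells in that tissue sample may be the source. The signal summed around the genes made no call for the lymphocyte (0.55, percentile 83.7) or macrophage list (-0.10, with 3 of 10 genes higher), Csf1r, Adgre1, Cx3cr1 and C1qa, of myeloid cells, had no promoter DHS in either library, and whether the cells came from the gland, blood or adjoining tissue stays open.

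The largest ratios of single genes went both ways at strong promoters. For all 10 genes, the promoter DHS overlapped between the libraries but was nearest to the gene in 1 library only, against 0.799% of 7886 other genes of above-median signal, with 8 distinct DHSs among the 10 genes. A candidate explanation is DHSs between close starts assigned to different genes in the 2 libraries.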
